A study of Mus musculus with 2 samples.

How the data were processed

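Single-cell transcriptomes were measured in the dentate gyrus of mice at postnatal day 30 with the 10x Genomics droplet assay, which tags each captured messenger RNA near its 3' end with a cell barcode and a unique molecular identifier (UMI). Per the labels, the 2 samples were a control (Nestin-Cre, Phf2+/+) and a conditional knockout (cKO; Nestin-Cre, Phf2flox/flox), with 4 mice per genotype, and cells were dissociated with an enzymatic neural tissue kit after perfusion with saline. The deposited values were raw UMI counts per gene and barcode, not normalized, in 1 unfiltered matrix of 32285 genes and 13589760 barcodes. Reads were processed with Cell Ranger 4.0.0 against mm10 and Scanpy 1.7.0 was used, per the submitters' processing notes. Whether reads were equalised between libraries when they were combined is not given in the sources used here.

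Each barcode ended in the suffix 1 or 2, with 6794880 barcodes per suffix. No label, header or barcode name tied a suffix to a genotype, and expression levels were not used to decide it. The suffixes are therefore called library 1 and library 2. They entered no comparison between genotypes, and the comparison of control with cKO by class and the medians of gene lists between genotypes were not made.

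Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes were kept. In library 1, 9441 barcodes passed the UMI minimum, 8516 also the gene minimum and 8255 also the mitochondrial limit. In library 2 these numbers were 9533, 8891 and 8381. Scrublet, run per library through scanpy 1.11.5 with an expected rate of 0.06, marked 226 barcodes (2.74%) in library 1 and 252 (3.01%) in library 2 as doublets, which were removed. Barcodes with fewer than 100 UMIs gave the profile of free RNA, from 5037003 UMIs in library 1 and 2955544 in library 2.

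The kept cells of both libraries were scaled to 10000 counts, log-transformed and clustered together on variable genes (3000 selected, 2995 used), 40 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial genes, sex-linked markers and the genes of the 5 tested lists were left out of clustering, so that these genes did not form the clusters they were compared between. No tested gene was a marker, but the 10 leading genes used in naming were ranked over all genes. The tested gene Chek1 was among the leading genes of cluster 19, which was named nIPC. The 33 clusters were named from markers of 25 classes chosen before the data were examined. A name needed at least 3 markers found in at least 25% of a cluster's cells, a mean log2 marker score of at least 1 (10 CPM added), and no unrelated class at 0.75 times the best score or more. Between related classes this close, the class with more markers among the 10 leading genes was taken, then the higher score. Shallow clusters with no own marker among their 10 leading genes stayed unnamed. The markers were fixed in advance, while these scoring details were set after seeing the data. They left 311 cells (3.87%) of library 1 and 331 (4.07%) of library 2 unnamed. Names such as RGL-like rest on these markers alone.

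Class shares were given per library with exact Clopper-Pearson 95% intervals. Phf2 was given as CPM, the counts of a gene scaled to a fixed total per class, computed from the deposited counts, with exact Poisson 95% intervals. Both cover counting error only. A class was reported with at least 20 cells per library. Cells with G2/M transcripts were those with at least 2 UMIs over 20 listed genes, before and after each cell was thinned at random to 1000 UMIs. No cell was left out by thinning, because the UMI minimum was the same.

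For 4 contrasts between classes, raw counts were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the 2-sided quasi-likelihood test with library as a block. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) were derived from the F statistic. The 2 libraries gave 1 residual degree of freedom per contrast, so the spread of a gene was mostly borrowed from other genes. The block holds genotype and library together. These p-values rest on how far the difference between classes varied between these 2 libraries, and not on the spread between mice. Sums per library and class ranged from 3739015 to 24959732 UMIs. Biological coefficients of variation were 0.0551, 0.0548, 0.107 and 0.0650 in the order in which the contrasts are reported.

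Only genes of the 5 tested lists (65 genes) are reported from these contrasts: the KDM7 family, H3K9 demethylases, H3K9 methylation writers and readers, other chromatin regulators and the DNA damage response. Phf2 is named first. Of each list, the text names up to 4 members with the smallest adjusted p among those that passed, then the largest fold, and gives counts for the rest. A gene outside this rule is named only where the text says that it was chosen after its values were seen. Fisher's exact test, added after seeing the data, compared the share of list genes called in each direction with the share among all genes tested (8 tests). Other gene lists were examined only in cells clustered with every list left out, also added after seeing the data. List members that are also class markers stayed in that clustering and were not tested, so some lists are covered only in part. Of all listed genes, 1 had no match and was not analysed here.

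The contrast procedure was tested on simulated counts with 200 genes changed by known folds, first at a dispersion of 0.02. The simulation held 1 dispersion for all genes and no library effect. In the data 71.5%, 49.7%, 70.3% and 81.0% of the genes tested were called, in the order in which the contrasts are reported. The simulated rates of recovery and false calls need not hold there. For nIPC with neuroblast against RGL (13191 genes tested) it recovered 18.4% of genes changed by 1.5-fold, 65.3% at 2-fold and 98% at 4-fold, and 2.78% of its calls were false. For RGL against astrocyte (12263 genes) it recovered 18.4%, 59.2% and 98.0% at these folds, with 8.16% of calls false. For astrocyte against oligodendrocyte (12198 genes) it recovered 16%, 62% and 98%, with 6.12% false. For astrocyte against microglia (13388 genes) it recovered 16.3%, 58% and 95.9%, with 5.76% false. That dispersion lay above the fitted ones. At the dispersion fitted to each contrast (0.00304, 0.00301, 0.0115 and 0.00422, in the same order), it recovered 57.1%, 46.9%, 22.4% and 67.3% of genes changed by 1.5-fold and 96%, 69.4%, 78% and 82% at 2-fold, and 4.40%, 7.19%, 5.81% and 1.71% of calls were false.

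Alternatives covered the cell filters, the mitochondrial limit, doublets kept, clustering resolution and components, subtraction of free RNA from Phf2, a minimum of 3 G2/M UMIs, DESeq2 1.42.0 in place of edgeR, no low count filter, no library block and each library alone. Total-count scaling, neuroblast-like cells alone, naming of clusters by best score alone, all lists left out of clustering, and the looser cell filter, the mitochondrial limit, the halved resolution and 20 components for the contrasts, and total-count scaling and DESeq2 for the other gene lists, were added after seeing the data. Gene positions came from GENCODE M21 on GRCm38 (mm10), matched by Ensembl identifier for 32235 of the 32285 genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9.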

Results

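Cells of the dentate gyrus, the hippocampal region in which stem cells keep producing granule neurons after birth, were profiled at postnatal day 30 by droplet single-cell RNA sequencing. The 2 samples were control mice (Nestin-Cre, Phf2+/+) and conditional knockouts (cKO; Nestin-Cre, Phf2flox/flox), with 4 mice per genotype and 1 library each. Phf2 encodes a histone demethylase of the KDM7 family that acts on H3K9me2, and the series asks how it bears on stem cells leaving a shallow quiescent state. Library 1 held 102897659 UMIs and library 2 held 107266420. After filtering, 8029 cells with a median of 8092 UMIs and 2798 genes remained in library 1, and 8129 cells with a median of 7232 UMIs and 2601 genes in library 2. The sources used here do not say which library is which genotype, so values are given for library 1 and library 2 and no direction by genotype is drawn. There was 1 library per genotype, cells are not replicates, and intervals cover counting error only.

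Phf2 transcripts (ENSMUSG00000038025, a protein-coding gene on the minus strand of chromosome 13, 48801750 to 48871119 in mm10) were found in every reported class of both libraries. Choroid plexus-like cells of library 1 and Erythroid-like cells of library 2 held 1 Phf2 UMI each, and no free-RNA share was estimated for these classes. In nIPC-like cells, the intermediate progenitors of granule neurons, Phf2 stood at 24.9 CPM in library 1 (95% exact Poisson interval 21.1 to 29.2) and 12.2 CPM in library 2 (9.17 to 15.8). In Cycling-like cells it stood at 24.4 CPM (19.4 to 30.3) and 11.8 CPM (8.40 to 16.1), and in Oligodendrocyte-like cells at 11.8 CPM (9.38 to 14.6) and 5.94 CPM (4.37 to 7.90). In these 3 classes the intervals of the 2 libraries did not overlap. In RGL-like cells, the radial glia-like stem cells, Phf2 stood at 16.6 CPM (12.7 to 21.3) and 13.3 CPM (10.3 to 16.9), in Neuroblast-like cells at 16.1 CPM (12.9 to 19.9) and 10.7 CPM (7.96 to 14.0), and in Astrocyte-like cells at 18.5 CPM (14.96 to 22.7) and 16.3 CPM (13.03 to 20.2), with overlapping intervals. Microglia-like cells had 22.2 CPM in both libraries, and Endothelial-like cells, the class with the most Phf2 among those with over 500 cells per library, had 29.4 and 29.7 CPM. Free RNA held 17.9 and 13.9 CPM. Subtracting free RNA left 25.02 and 12.1 CPM in nIPC-like cells. The deleted exons are not given in the sources used here, and tags at the 3' end need not report a deletion elsewhere in the gene, so these levels check no label.

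**Figure D1:**
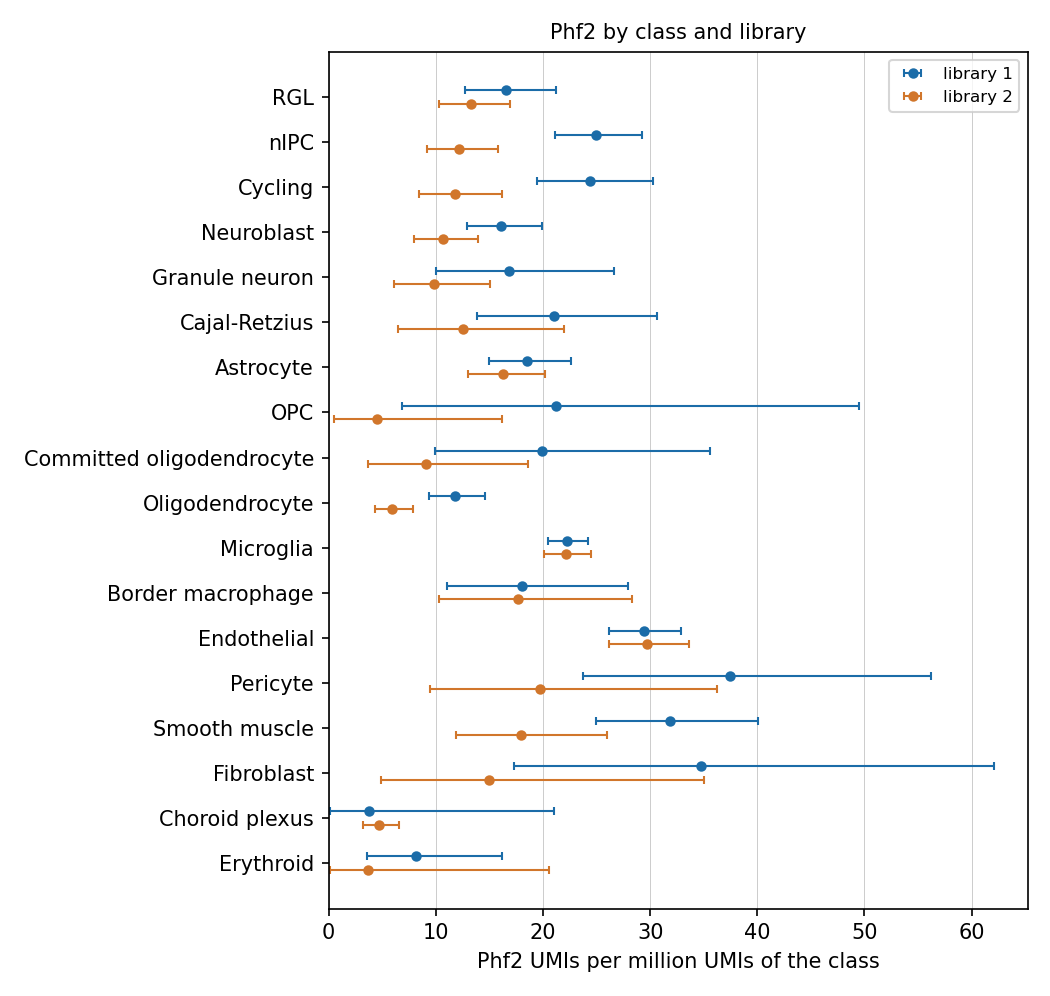
Phf2 level in CPM (horizontal axis) in each cell class and library, with points for the level and bars for the exact Poisson 95% interval. The intervals of library 1 and library 2 lie apart in nIPC (24.9 and 12.2 CPM), Cycling (24.4 and 11.8 CPM) and Oligodendrocyte (11.8 and 5.94 CPM) cells and coincide in Microglia (22.2 CPM in both).

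Class shares were counted over the dissociated cells that passed the filters and need not match the tissue. Granule neuron-like cells, for example, made up 0.610% of library 1 and 1.30% of library 2. Microglia-like cells were the most numerous named class, with 36.3% of library 1 (95% exact interval 35.3 to 37.4) and 30.4% of library 2 (29.4 to 31.4). Astrocyte-like cells made up 11.5% and 11.4%, and Endothelial-like cells 10.8% and 10.4%. RGL-like cells made up 6.95% of library 1 (6.40 to 7.53) and 9.73% of library 2 (9.09 to 10.4), nIPC-like cells 5.82% (5.31 to 6.35) and 5.01% (4.54 to 5.50), Neuroblast-like cells 7.87% (7.29 to 8.48) and 8.33% (7.74 to 8.95), and Cycling-like cells 2.65% (2.31 to 3.03) and 2.55% (2.21 to 2.91). Together these 4 neurogenic classes held 23.3% and 25.6%. Choroid plexus-like cells made up 0.361% of library 1 (29 cells) and 4.17% of library 2 (339 cells), and 111 of the 112 cells of their cluster 32 came from library 2.

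The leading genes of the clusters described these classes. Of the RGL-like cells, 457 and 661 lay in cluster 10, led by Frzb and Tnc, and 101 and 130 in cluster 6, a shallow cluster with a median of 1805 UMIs led by Riiad1 and Fabp7. The nIPC-like cells lay in cluster 0 (603 cells), led by Unc5d, Tac2 and Nhlh1 with Eomes, and in cluster 19 (271 cells), led by the S-phase genes Ung, Cdc6 and Uhrf1. Cluster 0 scored 2.59 for nIPC and 2.64 for Neuroblast and was named nIPC because 3 nIPC markers were among its 10 leading genes. Named by best score alone it would be Neuroblast, leaving 1.67% and 1.69% of cells as nIPC-like, with G2/M transcripts as below in 47.0% and 46.7%. Microglia-like cluster 8, with 1178 and 967 cells, was led by Tnfaip3, Il1a and Atf3, and cluster 13, with 460 and 502 cells, by the chemokine genes Ccl4 and Ccl3 with Tnf. No test between genotypes was possible. RGL-like cells made up 5.79% of library 1 and 7.96% of library 2 under a mitochondrial limit of 10%, and nIPC-like cells 4.13% and 3.51%.

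**Figure D2:**
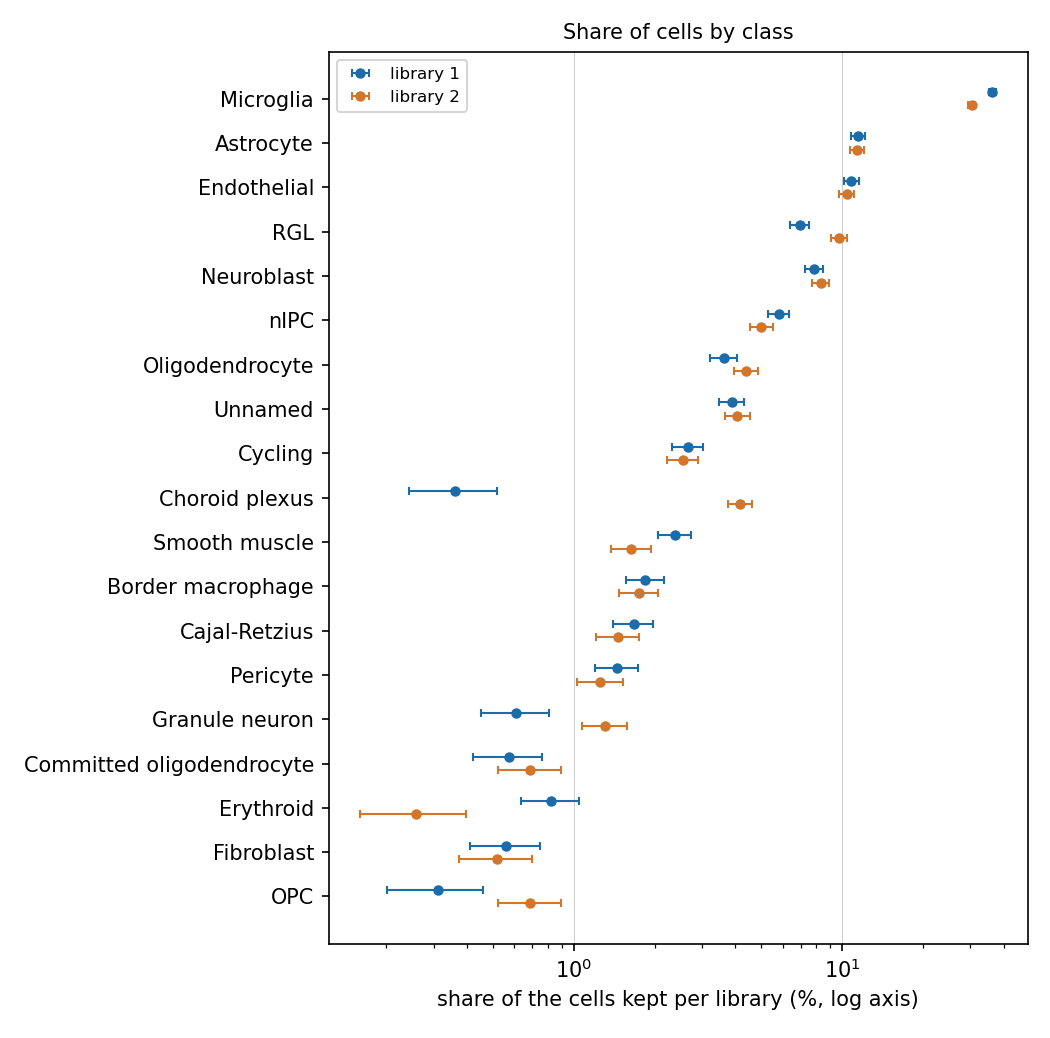
Share of the kept cells of each library in each class (percent, log axis), with exact binomial 95% intervals as bars. Shares range from 36.3% and 30.4% for Microglia to below 1% for OPC, and those of Choroid plexus (0.361% and 4.17%) lie farthest apart between the libraries.

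Outside the Cycling class itself, G2/M transcripts were most frequent in nIPC-like cells among the classes examined, mostly because of the S-phase cluster 19. At 1000 UMIs per cell, 18.0% of nIPC-like cells in library 1 (14.6 to 21.8) and 20.6% in library 2 (16.8 to 24.9) had at least 2 UMIs of the G2/M genes, which serve mitosis. In cluster 19 the share was 47.0% and 46.7%, while in cluster 0, which held most nIPC-like cells, it was 6.31% (3.95 to 9.48) and 7.41% (4.58 to 11.2), near Microglia-like cells (4.97% and 6.27%) and border macrophages (7.43% and 7.04%). In RGL-like cells the share was 3.41% (2.06 to 5.27) and 3.41% (2.26 to 4.93), and in Neuroblast-like cells 2.69% (1.57 to 4.27) and 2.51% (1.47 to 3.99). Within RGL it was 6.93% and 9.23% in the shallow cluster 6 and 2.63% and 2.27% in cluster 10. Within Neuroblast it was 8.87% and 7.65% in the shallow cluster 11 (median 2290 UMIs) and 1.18% and 0.789% in cluster 21. The share in Endothelial-like cells, a class taken as background, was 2.18% (1.32 to 3.39) and 2.24% (1.36 to 3.48), with median depths of 8384 and 7305 UMIs against 6820 and 6400 in RGL-like cells, so the RGL and Neuroblast shares could not be told from this class at this depth. That verdict depended on the class taken as background, since Astrocyte-like cells had 0.326% (0.067 to 0.95) and 0.649% (0.238 to 1.41), below the intervals of RGL, and Microglia-like cells had the higher values above. Oligodendrocyte-like cells, with median depths of 23807 and 21762 UMIs, had 0% (up to 1.26%) and 0.281%. Without thinning the shares were 83.3% and 80.1% in nIPC-like, 36.9% and 37.9% in RGL-like, 26.4% and 26.0% in Neuroblast-like, 53.1% and 52.7% in Endothelial-like, and 19.2% and 16.6% in Oligodendrocyte-like cells. A minimum of 3 UMIs gave 0.717% and 1.14% of RGL-like cells and 10.1% and 13.3% of nIPC-like cells.

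**Figure D3:**
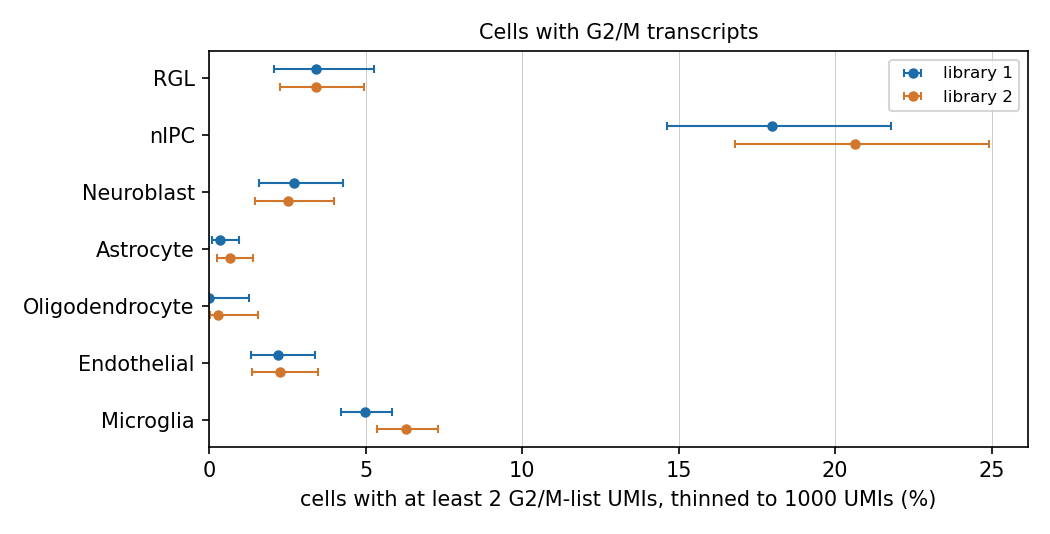
Percent of cells with at least 2 G2/M-list UMIs after thinning to 1000 UMIs per cell, by class and library, with exact binomial 95% intervals as bars. The nIPC shares (18.0% and 20.6%) lie above all other classes drawn and combine cluster 19 (47.0% and 46.7%) with cluster 0 (6.31% and 7.41%), while RGL (3.41% in both) and Neuroblast (2.69% and 2.51%) overlap the Endothelial background. Cells of the separate Cycling class are not drawn.

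The first contrast followed chromatin genes from stem cells to their committed progeny, nIPC-like with Neuroblast-like cells against RGL-like cells. Hdac2, a class I histone deacetylase, was higher in the progeny by 2.44 ± 0.10 on the log2 scale (SE, n = 2 libraries per class), with 215 and 206 CPM against 39.3 and 32.6 CPM in RGL. Ezh2, the H3K27 methyltransferase of Polycomb repressive complex 2, was higher by 1.97 ± 0.10, Smarca4, an ATPase of SWI/SNF remodelling complexes, by 1.76 ± 0.10, and Hdac9, a class IIa deacetylase, by 2.89 ± 0.18. Of the 24 other chromatin regulators, 12 were higher, 4 lower and 8 did not pass. Among 7 H3K9 demethylases, Kdm1a (1.85 ± 0.09), Kdm4a (1.45 ± 0.15) and Kdm3b (0.30 ± 0.13) were higher, Kdm3a was lower (−0.89 ± 0.13), and 3 did not pass. Of 12 writers and readers of H3K9 methylation, 8 were higher and 0 lower, led by Trim28 (1.53 ± 0.11), the scaffold that recruits SETDB1, the methyltransferase Ehmt1 (1.31 ± 0.11), the heterochromatin protein Cbx1 (0.84 ± 0.08) and the methyltransferase Suv39h2 (2.13 ± 0.24). In the KDM7 family Kdm7a was higher by 1.21 ± 0.11, while Phf2 differed by −0.04 ± 0.18 (adjusted p = 0.845) and Phf8 by −0.11 ± 0.17 (adjusted p = 0.584), neither past the threshold. Both went in opposite directions in the 2 libraries, Phf2 at 0.21 in library 1 and −0.36 in library 2 and Phf8 at 0.087 and −0.28, so each value averages opposite directions. In all 4 contrasts 1 of the 2 libraries came from cKO mice, so the Phf2 values average a control with a knockout of Phf2. How far each class carried the deletion was not tested. Of 18 DNA damage genes, 13 were higher, 2 lower and 3 did not pass, led by Trp53 (1.54 ± 0.11), Parp1 (1.25 ± 0.11), Gadd45a (2.29 ± 0.23) and the homologous recombination gene Brca1 (3.30 ± 0.33), which stood at 1.29 ± 0.50 (adjusted p = 0.041) with Neuroblast-like cells alone.

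In all, 37 of the 64 list genes tested were higher and 7 lower (edgeR, over 13442 genes), and the counts adjusted over the list alone were also 37 and 7. The 44 called genes had the same sign in both libraries. Here and in the later contrasts both libraries entered the test, so agreement in sign is no independent check of the calls. List genes were higher more often than all genes tested (57.8% against 36.0%, Fisher's exact test, adjusted p = 0.0011) and lower less often (10.9% against 35.5%, adjusted p = 8.5e-05), although genes are not independent. DESeq2 called 32 higher and 3 lower, without Kdm3b. With Neuroblast-like cells alone against RGL, 32 were higher and 6 lower, and 34 and 9 when cluster 0 counted as Neuroblast. Median mitochondrial shares were 4.78% and 5.69% in the progeny against 6.74% and 7.79% in RGL-like cells, and median depths 10384 and 8545 against 6820 and 6400 UMIs. In cells clustered with every list left out, 6 of 20 early response and dissociation stress genes were higher in the progeny and 10 lower.

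**Figure D4:**
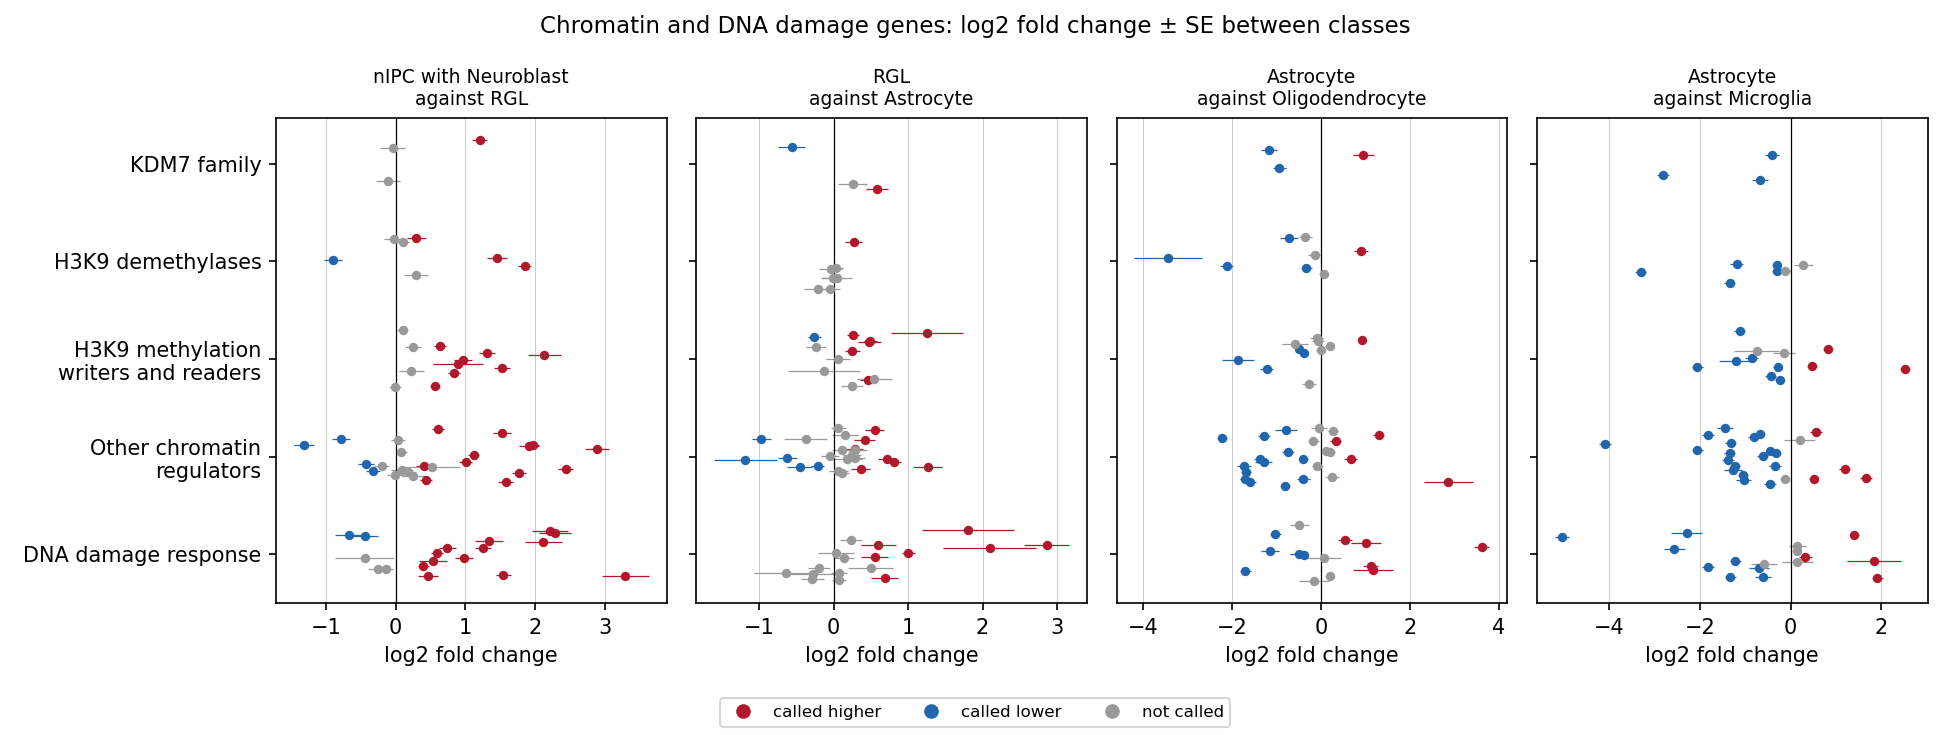
Log2 fold change (horizontal axes, points) with its SE (bars) for each tested gene of the 5 lists in the 4 contrasts between classes, coloured by whether the gene was called at an adjusted p of 0.05. Called genes lie mostly to the right in nIPC with Neuroblast against RGL (37 higher, 7 lower) and to the left in Astrocyte against Microglia (11 higher, 41 lower).

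The second contrast set RGL-like stem cells against Astrocyte-like cells, the mature astroglia. The histone H3K4 demethylase Kdm5b was higher in RGL by 0.81 ± 0.10 (SE, n = 2 libraries per class), the maintenance DNA methyltransferase Dnmt1 by 1.26 ± 0.20 and the remodeller Chd7 by 0.71 ± 0.11, while the DNA demethylation enzyme Tet2 was lower (−0.97 ± 0.13). Of the 24 other chromatin regulators, 7 were higher, 5 lower and 12 did not pass. Of 12 writers and readers, 6 were higher, led by the heterochromatin proteins Cbx5 (0.49 ± 0.09) and Cbx3 (0.26 ± 0.08) with Mphosph8 (0.46 ± 0.10) and Trim28 (0.48 ± 0.16), and 1 was lower. Kdm1a, at 0.27 ± 0.11, was the single H3K9 demethylase of 7 that passed. Phf2 was lower in RGL (−0.56 ± 0.18, adjusted p = 0.0099) and Kdm7a higher (0.58 ± 0.15), while Phf8 did not pass. Of 17 DNA damage genes, 7 were higher and 0 lower, led by Gadd45g (1.00 ± 0.09), the checkpoint kinases Chek2 (2.86 ± 0.30) and Chek1 (2.10 ± 0.62), and Atm (0.69 ± 0.18). The fold of Chek1 rested on 28 UMIs in RGL and 6 in astrocytes. In cells clustered with every list left out, 13 of 19 early response and dissociation stress genes were also higher in RGL. In the cells of this contrast the median mitochondrial share was 6.74% and 7.79% in RGL-like cells against 10.03% and 11.01% in Astrocyte-like cells.

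Of 63 list genes, 22 were higher and 7 lower (edgeR, over 12389 genes), also when adjusted over the list alone, and the 29 called genes had the same sign in both libraries. The list shares were 34.9% higher against 23.6% of all genes (Fisher's exact test, adjusted p = 0.043) and 11.1% lower against 26.2% (adjusted p = 0.0092). Total-count scaling moved the median of all genes by 0.34 and called 43 higher and 1 lower, so that 97.7% of its calls were higher against 75.9% with TMM, and the call of Phf2 was lost (−0.23). Atrx, the 1 writer or reader called lower, and Chd4 turned sign with it (−0.26 to 0.076 and −0.22 to 0.12, neither past the threshold; both chosen after their values were seen), while no called list gene turned sign with DESeq2. DESeq2 called 6 higher and 1 lower and lost Phf2 (−0.56 ± 0.43, the same fold with a larger SE), Kdm7a, Kdm1a, Mphosph8, Cbx3, Trim28, Atm and Chek1, and a mitochondrial limit of 10% left 14 higher and 7 lower. Of the 29 calls, that limit kept 21 and the test without the library block 20.

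The third contrast compared Astrocyte-like with Oligodendrocyte-like cells, a pair of glial classes outside the neurogenic lineage. The de novo DNA methyltransferase Dnmt3a was lower in astrocytes (−2.24 ± 0.11 on the log2 scale, SE, n = 2 libraries per class), as were Chd7 (−1.72 ± 0.10), the DNA demethylation enzyme Tet3 (−1.69 ± 0.11) and the H3K27 demethylase Kdm6a (−1.60 ± 0.13). Of the 24 other chromatin regulators, 4 were higher, 13 lower and 7 did not pass. Of 8 H3K9 demethylases, Kdm4a (−2.12 ± 0.15), Kdm4d (−3.44 ± 0.76) and 2 more were lower and Kdm3a was higher (0.89 ± 0.15). The fold of Kdm4d rested on 2 UMIs in astrocytes and 33 in oligodendrocytes. Of 11 writers and readers, Cbx5 was the 1 that was higher (0.92 ± 0.09), and 4 were lower, led by Trim28 (−1.23 ± 0.14) and Setdb2 (−1.87 ± 0.37). All 3 KDM7 members passed: Phf2 was higher in astrocytes (0.94 ± 0.23, adjusted p = 0.0049), and Kdm7a (−0.94 ± 0.14) and Phf8 (−1.17 ± 0.18) were lower. The Phf2 value averages a control with a cKO library, at 0.57 in library 1 and 1.40 in library 2. Of 14 DNA damage genes, 5 were higher and 5 lower, led by Gadd45g (3.61 ± 0.18; 4.05 in library 1 and 3.25 in library 2) and the Trp53 antagonist Mdm2 (−1.71 ± 0.13).

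Of 60 list genes, 12 were higher and 28 lower (edgeR, over 12533 genes), also when adjusted over the list alone, and the 40 called genes had the same sign in both libraries. The list shares were 20% higher against 35.9% of all genes (Fisher's exact test, adjusted p = 0.013) and 46.7% lower against 34.4% (adjusted p = 0.056). DESeq2 called 5 higher and 15 lower and lost Phf2 (0.95 ± 0.56), Kdm3a, Kdm4b, Kdm4d, Mphosph8 and Setdb2. Phf2 stood at 18.5 and 16.3 CPM in astrocytes against 11.8 and 5.94 CPM in oligodendrocytes. Median mitochondrial shares were 10.03% and 11.01% in Astrocyte-like against 6.40% and 7.18% in Oligodendrocyte-like cells, and median depths 4673 and 5064 against 23807 and 21762 UMIs. Of the 1845 astrocytes, 571 lay in the shallow cluster 9 (median 1807 UMIs, 13.9% mitochondrial). A mitochondrial limit of 10% kept 36 of the 40 calls.

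The last contrast compared Astrocyte-like cells with Microglia-like cells, the immune cells of the brain, which do not arise from neural stem cells. The H3K27 demethylase Kdm6b was lower in astrocytes (−4.08 ± 0.13 on the log2 scale, SE, n = 2 libraries per class), with 19.5 and 18.8 CPM against 279.9 and 348.6 CPM. Chd7 (−2.05 ± 0.11) and the Polycomb subunit Eed (−1.81 ± 0.14) were also lower, while Tet1 was higher (1.66 ± 0.13). Of the 24 other chromatin regulators, 4 were higher, 18 lower and 2 did not pass. Of 7 H3K9 demethylases 5 were lower, led by Jmjd1c (−3.30 ± 0.12), Kdm3b (−1.34 ± 0.12) and Kdm4a (−1.19 ± 0.15). Of 12 writers and readers, 3 were higher, led by Cbx5 (2.52 ± 0.11) and Cbx3 (0.82 ± 0.10), and 7 lower, led by Trim28 (−2.05 ± 0.13) and Setdb1 (−1.12 ± 0.12). Kdm7a (−2.81 ± 0.12), Phf8 (−0.67 ± 0.18) and Phf2 (−0.41 ± 0.15, adjusted p = 0.0080) were all lower in astrocytes. The Phf2 value again averages a control with a cKO library. Of 16 DNA damage genes, 4 were higher and 8 lower, led by the stress-induced Gadd45b (−5.04 ± 0.15) and the mTORC1 inhibitor Ddit4 (1.92 ± 0.12; 1.26 in library 1 and 2.87 in library 2).

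Of 62 list genes, 11 were higher and 41 lower (edgeR, over 13989 genes), also when adjusted over the list alone, and the 52 called genes had the same sign in both libraries. The list shares were 17.7% higher against 39.0% of all genes (Fisher's exact test, adjusted p = 0.0010) and 66.1% lower against 42.0% (adjusted p = 0.00058). DESeq2 called 6 higher and 28 lower and lost Phf2 (−0.43 ± 0.36), Phf8 and Kdm1a. Median mitochondrial shares were 10.03% and 11.01% in Astrocyte-like against 3.11% and 4.36% in Microglia-like cells, and a limit of 10% kept 43 of the 52 calls. In cells clustered with every list left out, the 20 genes of the early response and dissociation stress list, such as Fos and Jun, were all lower in astrocytes than in microglia.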

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

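The tests of explanations in this part, and the bounds they were read against, were chosen only after the results were seen. Values in free RNA, taken from barcodes with fewer than 100 UMIs that entered no comparison, lay above the 0.596 CPM in library 1 and 1.02 CPM in library 2 that a count of 0 allows. Ttr, the transthyretin gene of choroid plexus, stood there at 2041 CPM in library 1 and 20000 CPM in library 2. The haemoglobin gene Hbb-bs stood at 25331 CPM in library 1 and 13052 CPM in library 2, and Hba-a1 at 10834 and 6281 CPM, while Erythroid-like cells made up 0.822% of library 1 and 0.258% of library 2.

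Choroid plexus-like cells were 11.5 times as frequent in library 2 as in library 1. Free RNA taken up by other cells is argued against for the class as a sum, because Ttr in these cells of library 2 stood 15.6 times above its level in free RNA. Ttr was also 1 of the markers that named the class. The sum includes the deep cluster 32 (median 44302 UMIs), and cluster 2 (median 6032.5 UMIs), with 228 of the 339 cells of library 2, was not tested alone. Equal tissue with the cells of library 1 lost at capture or by the filters is argued against by a 9.80-fold higher Ttr level in the free RNA of library 2. More choroid plexus taken along in the dissection of library 2 may account for both, but with 1 library per genotype the share ratio of 11.5 cannot be told apart from an effect of genotype, which stays open and untested. In other cells of library 2, Ttr stood at 534 CPM in RGL-like and 339 CPM in Microglia-like cells, against 10.2 and 7.37 CPM in library 1.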

How the results depend on the processing

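Total-count scaling, Neuroblast-like cells alone, naming of clusters by best score alone, all lists left out of clustering and, for the contrasts, the looser cell filter, the 10% mitochondrial limit, halved resolution and 20 components, and both scalings of the other gene lists, were chosen only after the results were seen. Candidate technical causes were tested for the move of RGL against Astrocyte with total-count scaling, as given in the closing paragraph. The cause was not tested for any other move below, except where the setting itself removes cells or genes. The comparison of control with cKO by class and the list medians were not run under any alternative, because no library was tied to a genotype. No paired analysis of control and cKO was possible. There was 1 library per genotype, which gives no pairs even if each library were tied to a genotype. The class contrasts were blocked by library.

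Cells kept in libraries 1 and 2 were 8904 and 8715 with at least 500 UMIs and 300 genes, 7327 and 7451 with at least 2000 UMIs and 1000 genes, 7207 and 6760 with a 10% mitochondrial limit, and 8255 and 8381 with doublets kept. With 2000 UMIs and 1000 genes, the RGL share was 6.22% and 8.88%, nIPC 4.37% and 3.87%, Neuroblast 8.98% in library 1, and the neurogenic classes together 22.1% and 23.8%. With the 10% mitochondrial limit, RGL was 5.79% and 7.96%, nIPC 4.13% and 3.51%, Neuroblast 9.63% and 10.0%, Cycling 3.58% in both, and Phf2 in nIPC of library 1 was 21 CPM. With 20 components, RGL was 5.65% and 8.16%, Neuroblast 6.51% and 6.38%, and the neurogenic classes together 20.5% and 21.9%. With 500 UMIs and 300 genes nIPC was 5.18% and 4.53%. With resolution doubled, nIPC was 6.45% and Neuroblast 7.24% in library 1. Naming by best score alone turned cluster 0 from nIPC into Neuroblast, with nIPC at 1.67% and 1.69% and Neuroblast at 12.02% and 11.65%.

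The thinned cycling share of nIPC was 22.8% and 25.8% with 500 UMIs and 300 genes, 23.4% and 29.5% with 2000 UMIs and 1000 genes, 13.1% and 13.5% with the 10% mitochondrial limit, and 47.0% and 46.7% with naming by best score alone. In Neuroblast it was 1.22% and 0.630% with 2000 UMIs and 1000 genes, 1.15% and 0.771% with 20 components, and 0.968% in library 2 with 500 UMIs and 300 genes. With at least 3 G2/M UMIs it was 0.717% and 1.14% in RGL, 10.1% and 13.3% in nIPC, 1.11% and 0.886% in Neuroblast, and 14.3% and 13.1% over the neurogenic classes.

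With DESeq2, 3 list genes were lower in nIPC with Neuroblast than in RGL, 6 were higher and 1 lower in RGL than in Astrocyte, 5 higher and 15 lower in Astrocyte than in Oligodendrocyte, and 6 higher in Astrocyte than in Microglia. For RGL against Astrocyte, total-count scaling gave 43 higher and 1 lower, the 10% mitochondrial limit 14 higher, and no library block 4 lower. Of the genes called in the 4 contrasts, DESeq2 kept 35 of 44, 7 of 29, 20 of 40 and 34 of 52, the 10% mitochondrial limit 38, 21, 36 and 43, total-count scaling 42, 23, 37 and 49, and no library block 43, 20, 39 and 52. Among named genes, signs turned in tests for Phf2 in nIPC with Neuroblast against RGL without a low count filter (0.033), without the library block (0.016) and with total-count scaling (0.073), and for Phf8 there with total-count scaling (0.0085) and with Neuroblast alone under naming by best score alone (0.0068). None of these was past the threshold in any setting. Among other called list genes, Atrx (−0.26 to 0.076) and Chd4 (−0.22 to 0.12) turned sign in RGL against Astrocyte with total-count scaling, and Chek1 (2.22 to −0.0052) in nIPC with Neuroblast against RGL with Neuroblast alone under naming by best score alone, none past the threshold after the turn. The 2 libraries also differed in sign there, with Phf2 at 0.21 in library 1 and −0.36 in library 2, and Phf8 at 0.087 and −0.28. Among 73 values of named genes, DESeq2 ended 18 calls. Leaving out library 1 or library 2 kept the direction of each called list gene, while Ddit4 in Astrocyte against Microglia ranged from 1.26 to 2.87. The calls were made from these same libraries, so the kept directions are no independent check. With each main result counted once per alternative setting, 401 values stayed within their interval or within 1.5 times and 69 moved. Of values for single classes, lists and genes, 196 class shares stayed and 44 moved, 97 cycling shares stayed and 47 moved, and 656 counts per list stayed and 68 moved, while 1017 gene values stayed, 30 lost their call, 1 gained it (Phf8 in RGL against Astrocyte with total-count scaling), 6 moved when a library was left out and 5 turned sign in a test as given above. Phf2 rested on counts such as 62 and 66 UMIs in RGL.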

Other observations

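All tests in this part were chosen only after the results were seen. Gene groups beyond chromatin were compared in cells clustered with every list left out (edgeR, n = 2 libraries per class), where 35.9% of all genes were higher and 35.6% lower in nIPC-like with Neuroblast-like cells than in RGL-like cells. List members that are also class markers stayed in that clustering and are not among the genes counted here. All 20 S-phase genes were higher in the progeny, led by the replicative helicase genes Mcm6 (2.64 ± 0.13, log2 ± SE) and Mcm7 (2.14 ± 0.11), and 12 of 13 G2/M genes were higher. In the main clustering the nIPC-like cells included cluster 19, which was itself led by S-phase genes. The S-phase and G2/M counts were not repeated with Neuroblast-like cells alone, so they do not describe the progeny apart from such cells. Of 15 Notch and BMP genes, 11 were lower, among them Id3 (−5.24 ± 0.10), Hes1 (−5.49 ± 0.15) and Notch2 (−4.13 ± 0.11), and 4 were higher. Of 24 quiescence genes, 15 were lower, among them Id4 (−4.92 ± 0.09), Clu (−5.31 ± 0.09) and Apoe (−5.06 ± 0.07), and 7 were higher. Id1, Id3, Hes1, Notch1, Notch2 and Bmpr1a, all lower, are on both the Notch and BMP and the quiescence list and are counted in each. The activation list went both ways, with 8 of 14 genes higher, among them Cdk4 (2.22 ± 0.09) and Cdk6 (2.13 ± 0.10), and 3 lower, among them Fabp7 (−4.40 ± 0.08) and Dbi (−4.13 ± 0.07), which stem cells also express. Of 18 lipid metabolism genes, 14 were lower, such as Acadl (−3.40 ± 0.11) of fatty acid oxidation and Scd2 (−2.32 ± 0.08) of fatty acid desaturation. Of 7 reactive astrocyte genes all were lower, led by Gfap (−4.77 ± 0.10). All 6 astrocyte homeostasis genes tested were lower too, with a median of −4.42 against −2.62 for the reactive list, so the difference was not particular to reactive genes. Total-count scaling left 6 of the 7 reactive genes lower, and DESeq2 5 of 8, with 9 of 13 G2/M genes and 19 of 20 S-phase genes higher.

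RGL-like cells carried more interferon response transcripts than Astrocyte-like cells. All 10 genes tested of the 12 on that list were higher, led by Ifit3 (4.27 ± 0.25), with 28.4 and 52.9 CPM in RGL against 1.77 and 1.53 CPM in astrocytes, and Ifitm3 (1.31 ± 0.12), while 10 of 11 were lower in the progeny than in RGL (Ifit3 −6.96 ± 0.29). Lipid metabolism genes were lower in RGL than in astrocytes for 16 of 18, among them Fabp5 (−1.14 ± 0.07) and Elovl5 (−1.39 ± 0.09). Activation genes were higher for 11 of 14, led by Ccnd2 (2.24 ± 0.11) and Btg2 (1.956 ± 0.106), S-phase genes for 11 of 15, and early response genes for 13 of 19, led by Fos (3.47 ± 0.10). Btg2 is on both the activation and the early response list and is counted in each. In these lists 2 activation and 3 early response genes were lower. Of 24 quiescence genes 9 were higher and 11 lower, and of 16 Notch and BMP genes 7 and 5, with the genes shared by these lists counted in each. Among all genes tested in this contrast, 23.6% were higher and 26.1% lower. Total-count scaling moved the median of all genes by 0.33 in this contrast and gave 10 interferon genes and 14 S-phase genes higher and 14 lipid genes lower, while DESeq2 gave 6, 2 and 13.

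List genes were mostly higher in nIPC-like with Neuroblast-like cells than in RGL-like cells, and S-phase and dividing cells among nIPC might account for it. For the chromatin lists this is argued against as the whole cause, because 22 of the 24 genes called higher stayed so with Neuroblast-like cells alone, Hdac2 at 2.45 and Ezh2 at 1.69. The other 2 were Chd7, which went from 1.00 to 0.21, and Setdb2, from 0.90 to 0.41. For the DNA damage list 9 of 13 stayed higher, a number between the bounds set for either answer, so the part played by dividing cells cannot be told apart from that of the class. Brca1 went from 3.30 to 1.29, Chek1 from 2.22 to 0.15 and Brca2 from 1.33 to 0.13, examples chosen after their values were seen. No other biological explanation was tested.

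The counts for RGL against Astrocyte depended on scaling, and the most abundant genes taking a larger share of astrocyte counts is a candidate explanation. The log2 scaling factor between the classes was 0.34 with all genes and 0.12 without the mitochondrial genes and the 50 most abundant genes of each sum, which took 41.5% and 42.8% of astrocyte counts against 32.5% and 33.3% of RGL counts. Mitochondrial genes alone are argued against, since the factor stayed at 0.29 without them. The same removal raised the factor from 0.06 to 0.38 in Astrocyte against Microglia, so it does not make scalings meet in general. No biological explanation was tested.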
